A study of Macaca mulatta with 16 samples.

How the data were processed

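ATAC-seq libraries were made from 10000 sorted cells per population of peripheral blood with 11 to 15 cycles of amplification, per the labels' protocols. The titles name 2 animals, each with 4 populations at 2 times, which gives 16 libraries. File names number the second animal differently for each of its 4 populations, while the titles give it one name, and the titles were followed. If the numbers meant different animals, animal and population would coincide in 8 of the 16 libraries. The pairing across populations would then not hold there, while before-after pairs would. The mean Jaccard index of libraries that differed in lineage was 0.744 ± 0.0372 (SD, n = 4) within animal 2, 0.729 ± 0.0231 (SD, n = 4) within animal 1 and 0.710 ± 0.0279 (SD, n = 8) between them. For state it was 0.708 ± 0.0539, 0.713 ± 0.0488 and 0.688 ± 0.0452, with overlapping ranges that do not decide this. Names and versions in the submitters' processing notes are cutadapt 1.18, Bowtie2 2.3.4.1 and Genrich 0.6, with the build rheMac10. Their settings, any shift of reads for transposase binding, duplicate removal and the chromosomes excluded are not given in the sources used here. The deposited lists were 1 per library, so replicates had been called separately and not pooled. Peaks lay on 21 chromosomes, the 20 autosomes and X.

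Each deposited list gives a peak's area score, the score of the authors' caller, whose lowest value in any list was 200.0. Each also gives the −log10 p at the summit as deposited by the authors, from 2.42 to 16.3, without a q value. Scores and −log10 values belong to their own list, so they were used only to rank or filter peaks within a list. Counts of reads were not used here and depth was unknown, which means that a list can be longer because its library was deeper. Lists held 36307 to 42034 peaks (median 40452), with median widths of 1036 to 1228 bp.

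Peaks of all lists that shared at least 1 bp were merged into regions, and a region was open in a library that had a peak in it. Regions open in 5 to 11 of the 16 libraries were tested with Fisher's exact test, two-sided, on 8 against 8 libraries, with Benjamini-Hochberg adjustment over 10922 regions and a threshold of 0.05. The 8 libraries of a side came from 2 animals, so these p-values measure the spread between libraries and not between many animals. Pairing came from the titles, since the same 2 animals gave every population at both times, and not from the peak sets. The mean Jaccard index was slightly higher within an animal than between animals (0.736 against 0.710 for libraries that differed in lineage, 0.710 against 0.688 for state), but the ranges overlapped, as given above. The paired version was the exact McNemar test over 8 matched pairs. An exact test with the animals as strata kept the animals apart but did not match libraries within an animal. Within a lineage or state, regions open in 4 of 4 libraries of one side and 0 of 4 of the other were counted and set against all 35 splits of the 8 libraries. In each population, regions gained in both or lost in both animals were counted beside those gained in one and lost in the other. Numbers of peaks, bases covered, median width and share on X were compared by exact sign-flip tests over 8 pairs. Peak sets were compared by the Jaccard index of bedtools 2.31.1 for all pairs of libraries. The 2 most similar libraries differed in 4069 regions, so no 2 lists were alike enough to be one library.

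Regions named in the text followed a rule fixed before the data were examined. In each comparison and direction it took up to 5 regions past the threshold by the difference in number of libraries, with ties broken by the mean percentile of the area score within its list. Where none passed, the first 5 by the same ranking were named as not passing. The comparison of animals and the groups of regions, joined where called regions were at most 50 kb apart, with the shuffles and random draws for them, were added after the data were examined.

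Planned results that need a genome or gene annotation of rheMac10 were not run, because the gene table at hand is of another assembly and its positions cannot be used with these. These were the tests of peaks per gene, 15 gene lists (including markers of other blood cells), 16 sequence motifs, and the share of peaks at promoters. Alternatives tried were lists of equal length (the 36307 peaks of highest area score in each), a stricter threshold (summit −log10 p of at least 3.42) and coverage of at least 50% of a region. Others were windows of 500 bp around summits, autosomes only and no filter on the number of libraries. The McNemar test, the test with animals as strata, each animal alone and each library left out were also run. Exact tests were checked against scipy, and the region test was tested on simulated data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, with a random seed of 1.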

Results

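Open chromatin was mapped by ATAC-seq, which cuts accessible DNA with a transposase, in T cells sorted from the blood of 2 rhesus macaques. Each animal was sampled before and after subcutaneous 2-hydroxypropyl-beta-cyclodextrin, a ring-shaped sugar that binds cholesterol. The dose was 1 ml/kg of a 15% (w/w) solution each day for up to 120 days. At each time 4 populations were sorted, namely naive and memory CD4+ T cells and naive and memory CD8+ T cells. Naive T cells have not yet met their antigen, and memory T cells descend from cells that have. This gave 16 libraries in 8 groups of 2, with 1 library per animal in each group. Every library was deposited as a list of 36307 to 42034 peaks, the stretches called open, which covered 51.4 to 66.3 Mb. Read depth behind the lists was unknown, so a missing peak was not detected in that list and was not shown to be closed chromatin. Overlapping peaks of all lists formed 55449 regions, of which 24333 (43.9%) were open in all 16 libraries and 5674 (10.2%) in 1. Positions are given in rheMac10, and genes at them are not given because no annotation of that build was used.

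Peak sets of one population of one animal before and after treatment were on average more alike than those of any other relation measured. Their Jaccard index, the bases shared by 2 lists over the bases in either, was 0.810 ± 0.0233 (SD, n = 8 library pairs). It was 0.775 ± 0.0340 (SD, n = 8) between the 2 animals, 0.736 ± 0.0298 (SD, n = 8) between CD4+ and CD8+ cells, and 0.710 ± 0.0477 (SD, n = 8) between naive and memory cells. For 14 of the 16 libraries the most similar list was that of the same population and animal at the other time. Similarity between times exceeded that between animals in all 4 populations, by 0.0347 ± 0.0181 (SD, n = 4). The exact two-sided sign-flip test gave p = 0.125, the smallest that 4 populations allow.

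**Figure D1:**
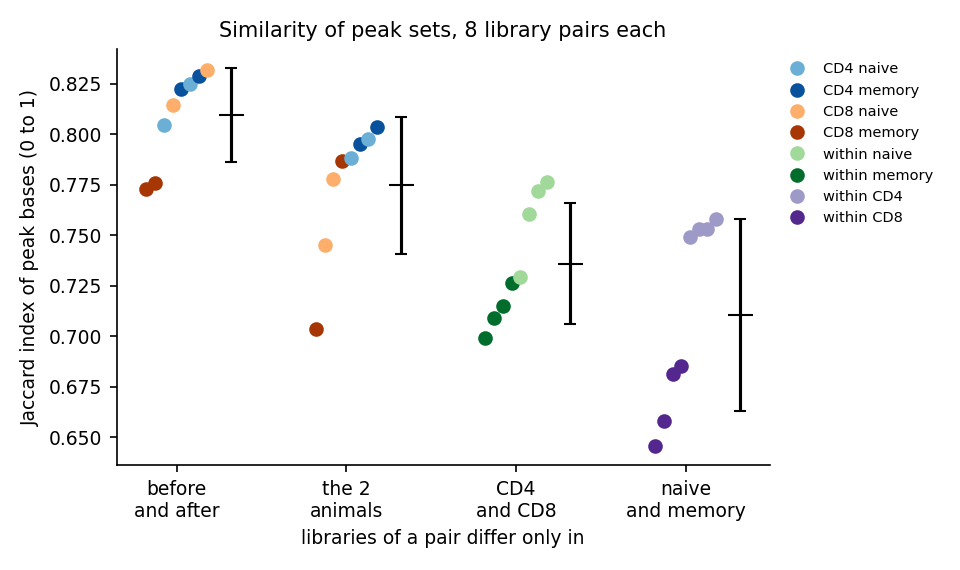
Jaccard index of peak bases (vertical axis, no unit) for library pairs that differ only in time, animal, lineage or state (horizontal axis). Points are the 8 library pairs of each kind, coloured by the population, state or lineage both libraries share, and bars show mean ± SD. Pairs that differ only in time average 0.810, and pairs that differ only in state average 0.710 and split into CD4+ pairs near 0.754 and CD8+ pairs near 0.667.

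The treatment comparison asked which regions opened or closed in T cells during cyclodextrin dosing. No region passed the test in either direction when the 8 libraries taken after treatment were set against the 8 taken before. The most uneven region after treatment lay on chromosome 3 at 175344915 to 175345367 and was open in 8 of 8 libraries after and 1 of 8 before. It did not pass adjustment (Fisher's exact test, two-sided, p = 0.00140, Benjamini-Hochberg adjusted p = 1.0 over 10922 regions). The next after-treatment regions, likewise not past the threshold, were on chromosome 2 at 54688608 to 54690313 (8 of 8 against 2 of 8), chromosome 10 at 98960135 to 98961652 (7 against 1), chromosome 20 at 75852776 to 75853631 (8 against 2) and chromosome 8 at 47824518 to 47825139 (7 against 1). Regions seen more often before treatment, also not past the threshold, were on chromosome 5 at 101012660 to 101014112 and at 101223456 to 101224104, and on chromosome 17 at 19343670 to 19345650. Each of these 3 was open in 7 of 8 libraries before and 2 of 8 after. The list was completed by chromosome 4 at 143412639 to 143413895 (8 against 3) and chromosome 9 at 58504292 to 58505170 (5 against 0). All 10 were weak peaks, with a mean area score between the 8.91st and the 18.7th percentile of their own lists. At an unadjusted p under 0.05 there were 42 regions, 30 open more often after and 12 more often before. The exact McNemar test over the 8 before-after pairs called 0, with 9 regions at an unadjusted p under 0.05, and a test with the animals as strata also called 0. At the smallest p, that of a region separating all 8 libraries from the other 8, a call needed 34 such regions, and there were 0. In simulations of this comparison over 10922 regions, all of 200 regions that switched in every library were recovered. Of regions in the stated condition in 90% of libraries 13.95% were recovered, and at 80% none were. Changes shared by 80% of libraries were thus not detectable with 200 changed regions. Other numbers of changed regions were not simulated, and the adjustment depends on that number. In the comparison of naive with memory cells below, where many regions differed, regions open in 8 of 8 against 2 of 8 libraries passed the same test. No untreated animals were sampled at both times, so time and treatment coincided.

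Single populations gained and lost peaks over treatment in each animal, and in 1 of the 4 populations the 2 animals changed in the same direction more often than in opposite directions. In naive CD4+ cells 262 regions were gained in both animals and 331 lost in both, a sum of 593, against 477 gained in one and lost in the other. Memory CD4+ cells had 393 gained and 185 lost in both, a sum of 578, against 579 in opposite directions. Naive CD8+ cells had 209 gained and 167 lost in both, a sum of 376, against 378. Memory CD8+ cells had 280 gained and 331 lost in both, a sum of 611, against 764. The ratio of same to opposite changes ran from 0.800 in memory CD8+ to 1.24 in naive CD4+ cells. With lists of equal length same changes were the more frequent in 3 populations, with ratios from 0.793 to 1.39. No test was made of these counts, since with 2 before-after pairs, 1 per animal, the smallest exact two-sided sign-flip p is 0.5.

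**Figure D2:**
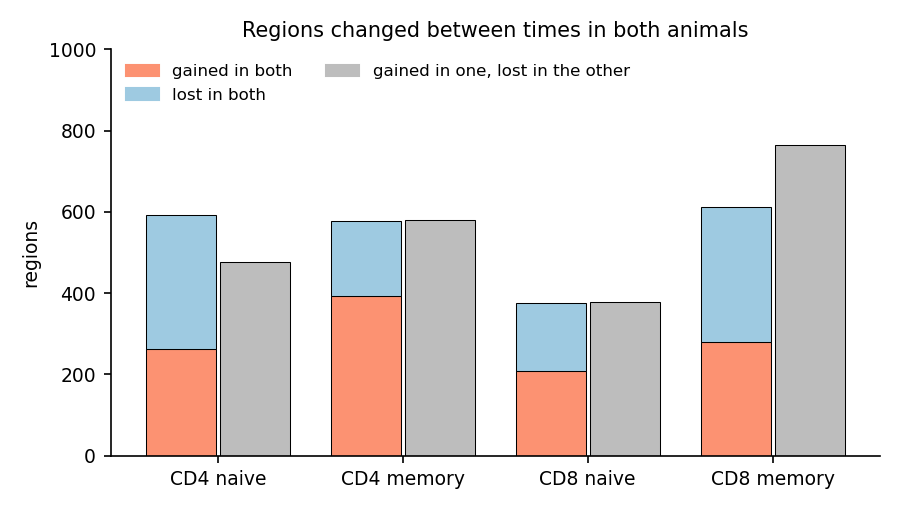
Regions that changed between the times in both animals (vertical axis, number of regions) for each T cell population (horizontal axis). Stacked bars are regions gained in both or lost in both animals, and grey bars are regions gained in one animal and lost in the other. Same-direction sums range from 376 to 611 and opposite-direction counts from 378 to 764.

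No difference in the number of peaks per library between the times passed the test. It was 40000 ± 1577 (SD, n = 8) before and 40266 ± 1255 (SD, n = 8) after, and rose in 4 of the 8 pairs (exact sign-flip test, two-sided, p = 0.555, adjusted p = 0.634 over 16 tests). Memory CD4+ cells of animal 1 gained the most, 2367 peaks, and memory CD8+ cells went from 40316 to 39426 peaks in animal 1 and from 40744 to 39519 in animal 2. Bases covered were 60.4 ± 4.81 Mb (SD, n = 8) before and 59.0 ± 3.49 Mb (SD, n = 8) after, higher after in 3 of 8 pairs (exact sign-flip p = 0.398, adjusted p = 0.580). In memory CD8+ cells, unlike the number of peaks, they rose from 55.4 to 63.1 Mb in animal 1 and fell from 66.3 to 59.6 Mb in animal 2. Without the memory CD4+ pair of animal 1, the mean change of 265.5 peaks became -34.7. Memory libraries covered more bases than naive ones, 61.7 ± 3.23 against 57.8 ± 4.19 Mb (SD, n = 8 each), in 7 of 8 pairs, with exact sign-flip p = 0.0156 that did not pass adjustment (adjusted p = 0.125).

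The comparison of naive with memory cells asked which regions mark the step from the one to the other in both lineages. Of 10922 tested regions 2930 differed, 1315 open in more naive libraries and 1615 in more memory libraries. Complete separation, in 8 of 8 libraries of one state and 0 of 8 of the other, was seen for 369 naive and 472 memory regions. The strongest peaks among the naive ones were on chromosome 5 at 143099321 to 143102285, chromosome 2 at 127381193 to 127384418, chromosome 19 at 1849058 to 1850983, chromosome 15 at 112908526 to 112911792 and chromosome 3 at 173072459 to 173074131. Among the memory regions the strongest were on chromosome 8 at 79272447 to 79275200, chromosome 16 at 41687896 to 41690190 and at 35020843 to 35022967, chromosome 13 at 14738248 to 14741308 and chromosome 6 at 154946036 to 154948833. Each of these 10 separated 8 libraries from 8 (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00202). Their mean area scores lay between the 64.2nd and the 75.5th percentile of their lists.

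Regions that differed between naive and memory cells and lay near each other mostly had the same direction. Of the 2930, 1759 had no other such region within 50 kb and 1171 (40.0%) had one, against 29.4% on average and 33.1% at most when as many tested regions were drawn at random 1000 times. Of 730 neighbouring pairs of such regions at most 50 kb apart, 91.8% had the same direction, against 50.6% on average and 56.3% at most in 1000 shuffles of the directions. The group with the most such regions was a stretch of 180.4 kb on chromosome 4, from 83121696 to 83302066. The stretch held 42 regions, 4 of them open in all 16 libraries. The 16 that passed the test were all open in more naive libraries. Memory groups included 11 regions on chromosome 2 from 161931659 to 162045294, where no region was open in all 16 libraries. Others were 9 regions on chromosome 4 from 3515637 to 3654525, 8 on chromosome 6 from 154921352 to 155007465 and 8 on chromosome 14 from 28979110 to 29172480. A group of 8 on chromosome 13 from 14649546 to 14741308 held 7 memory regions and 1 naive region.

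The state difference held when regions were chosen in one animal and read in the other. In animal 1, 755 regions were open in all 4 naive and no memory library and 1136 the other way, and in animal 2 these numbers were 1168 and 976. Memory regions of the other animal were open in 84.7% ± 5.45 of cases in memory libraries (SD, n = 8) and in 11.5% ± 2.61 in naive libraries (SD, n = 8). Naive regions of the other animal were open in 77.2% ± 13.8 of cases in naive libraries (SD, n = 8) and in 10.7% ± 4.50 in memory libraries (SD, n = 8). The lowest naive values were those of naive CD8+ cells of animal 1, with 52.3% before and 62.9% after treatment, against 92.6% and 92.1% in animal 2. The sets differed, since animal 1 was read on 1168 regions and animal 2 on 755. The 755 had to be open in the naive CD8+ lists of animal 1, so the animals are not compared like for like. The 2 naive CD8+ libraries of animal 1 also had the shortest lists, 36307 and 37966 peaks. With them left aside, 3017 regions differed between naive and memory cells and 768 between CD4+ and CD8+ cells. The exact McNemar test over the 8 matched pairs called 0 regions in the state comparison, since its smallest p of 0.00781 would need 1707 regions at that value, while 2928 regions had an unadjusted p under 0.05 and the exact test with animals as strata called 3191. Without the filter on the number of libraries the count fell to 1664.

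**Figure D3:**
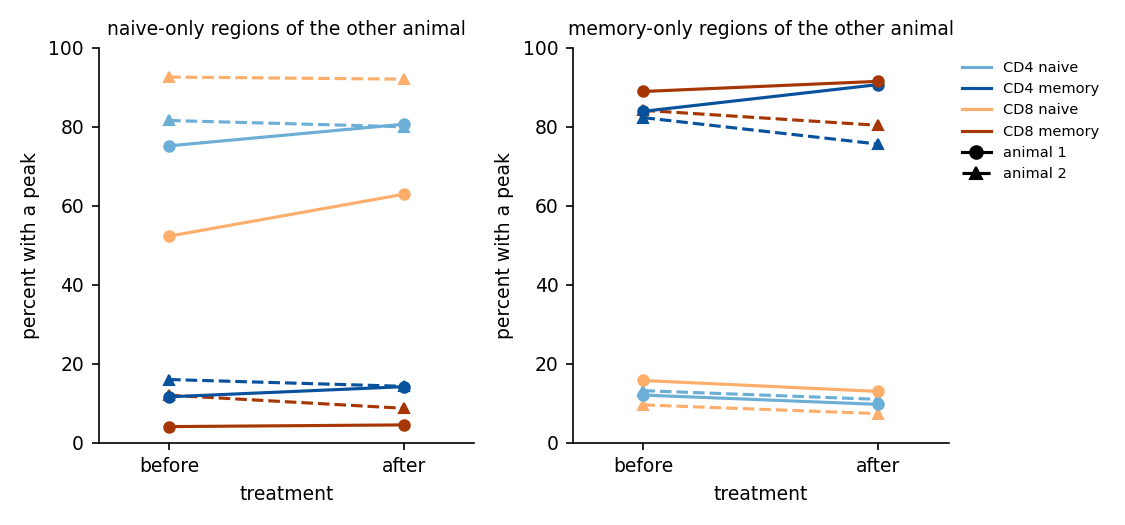
Percent of regions with a peak (vertical axes) before and after treatment (horizontal axes), for regions that were open in all 4 naive and no memory library of the other animal (left) or the reverse (right). Each line joins the 2 libraries of one population of one animal. Memory regions are open in 75.6% to 91.5% of cases in memory libraries and in 7.39% to 15.8% in naive libraries.

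The lineage comparison asked which regions separate CD4+ helper cells from CD8+ cytotoxic cells. It gave 783 regions, 437 open in more CD4+ libraries and 346 in more CD8+ libraries, and 173 and 206 of all regions separated the lineages completely. CD4+ regions with the strongest peaks were on chromosome 10 at 88198767 to 88203069, chromosome 8 at 48443846 to 48445961, chromosome 4 at 46539667 to 46541861, chromosome 3 at 38533110 to 38537619 and chromosome 9 at 1077795 to 1079298. CD8+ regions with the strongest peaks were on chromosome 13 at 19023326 to 19027550, chromosome 11 at 9365436 to 9368980 and at 9353139 to 9357692, chromosome 9 at 97139529 to 97144289 and chromosome 7 at 27565598 to 27571281. Each was open in 8 of 8 libraries of its lineage and 0 of 8 of the other (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.00448). Peaks of the CD8+ regions ranked high in their lists, from the 79.1st to the 91.2nd percentile of area score, and those of the CD4+ regions from the 57.9th to the 83.6th.

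Most lineage regions, 598 of 783, had no other lineage region within 50 kb. The other 185 (23.6%) had one, against 9.57% on average and 14.2% at most in random draws of tested regions, and 98.3% of the neighbouring pairs had the same direction, against 50.8% on average in shuffles. The largest CD8+ group held 8 regions over 129.1 kb on chromosome 11, from 9353139 to 9482204, where none of 22 regions was open in all libraries. Further CD8+ groups were 6 regions on chromosome 13 from 19023326 to 19118047 and 5 on chromosome 9 from 97064455 to 97144289. CD4+ groups held 7 regions on chromosome X from 132717158 to 132806730 and 6 on chromosome 1 from 96497630 to 96640085. The exact McNemar test called 0 regions here, with 1555 at an unadjusted p under 0.05, for the reason given for the states. The test with animals as strata called 783, and without the filter on the number of libraries 379 were called. Leaving out any 1 library raised the count, to at least 818, and the rise was largest for 5 CD8+ libraries. In animal 1 the count was 1636 without memory before, 1570 without memory after and 1735 without naive after treatment. In animal 2 it was 1848 without naive before and 1878 without naive after treatment. With any other library left out it was 818 to 865, and no count lay between 865 and 1570. Regions with the same p pass or fail the adjustment together, so the count can jump. These higher counts therefore do not show that a library masked a difference between lineages.

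**Figure D4:**
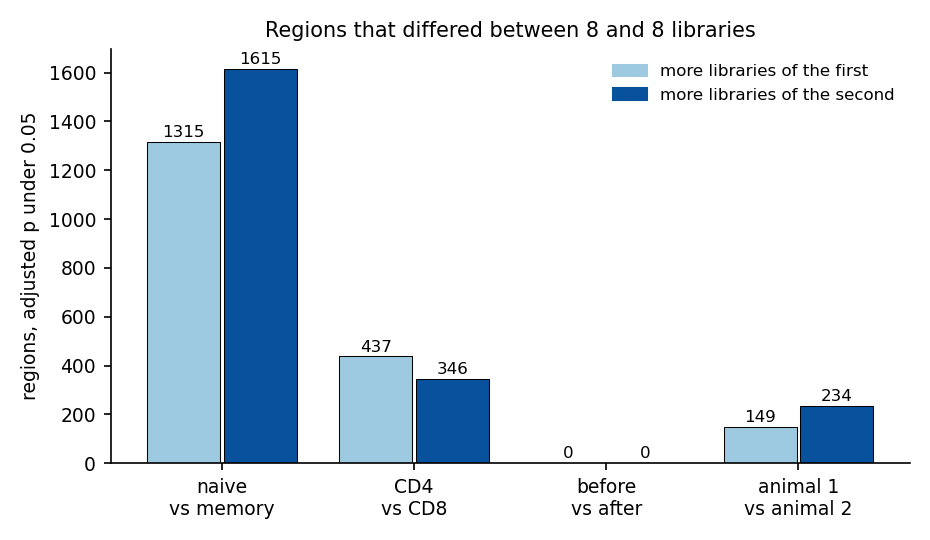
Number of regions with a Benjamini-Hochberg adjusted p under 0.05 in Fisher's exact test (vertical axis) for 4 comparisons of 8 with 8 libraries (horizontal axis). Light bars are regions open in more libraries of the first-named side and dark bars those of the second. The treatment comparison has 0 in both directions, and the state comparison has 1315 and 1615. The unadjusted p needed to pass was not the same in each comparison, since the adjustment depends on how many regions have a small p.

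More regions separated the states in CD8+ than in CD4+ cells, and more separated the lineages in memory than in naive cells. In CD4+ cells 991 regions were open in 4 of 4 naive and 0 of 4 memory libraries and 1353 the other way. In CD8+ cells these counts were 1713 and 2401. Among naive cells 764 regions were open in CD4+ libraries alone and 735 in CD8+ libraries alone, and among memory cells 1512 and 1596. At the stricter threshold 4 of these counts fell by over 1.5 times, to 832 memory and 1113 naive regions in CD4+ and CD8+ cells, and to 454 CD8+ and 993 CD4+ regions in naive and memory cells. No region switched direction, since 0 regions were naive in one lineage and memory in the other. Over the 31116 regions not open in all libraries, the lineages shared 369 naive regions, where independent sets would share 54.6, and 472 memory regions, where independent sets would share 104.4. The 31116 include regions that could not separate 4 libraries from 4, such as the 5674 open in 1 library. The numbers for independent sets are therefore too low, by an amount that was not computed. The Jaccard index of naive with memory peak sets was 0.667 ± 0.0189 (SD, n = 4) in CD8+ cells and 0.754 ± 0.00364 (SD, n = 4) in CD4+ cells. Between CD4+ and CD8+ peak sets it was 0.712 ± 0.0112 (SD, n = 4) in memory cells and 0.760 ± 0.0212 (SD, n = 4) in naive cells. Both differences had an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 allows, and adjusted p = 0.100 over 7 such tests, which is not past the threshold. The 4 values of a side came from 2 animals at 2 times, and the test ignored their matching to the other side. An exact sign-flip test over 4 pairs could not go below 0.125.

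Memory CD8+ cells had the most regions of their own. Regions open in all 4 libraries of a population and none of the others numbered 944 in memory CD8+, 212 in naive CD8+ and 168 in memory CD4+ cells. Regions missing from 1 population alone numbered 461 in memory CD8+, 141 in naive CD8+ and 32 in memory CD4+ cells. Naive CD4+ cells had 245 regions of either kind, against 1405 in memory CD8+, 353 in naive CD8+ and 200 in memory CD4+ cells. The difference in these counts between populations was not tested.

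The 2 animals differed in 383 regions, 149 open in more libraries of animal 1 and 234 in more of animal 2, in a comparison of 8 libraries of each that concerns these 2 animals alone, as the titles name them. The largest group was 20 regions on chromosome 7 from 168923605 to 169148150, all open in more libraries of animal 2. Another 14 lay on chromosome X from 127951254 to 128063788 and 4 on chromosome X from 56596790 to 56619569, all in animal 2. Animal 1 had 6 on chromosome 4 from 140469544 to 140531856. One region on chromosome X, at 112231437 to 112234868, was open in 8 of 8 libraries of animal 2 at the 99.9th percentile of area score and in 0 of 8 of animal 1 (Fisher's exact test, two-sided, adjusted p = 0.00793). Of the regions higher in animal 2, 31 of 234 lay on chromosome X, against 3 of 149 of those higher in animal 1 (Fisher's exact test, two-sided, p = 7.14e-05), although regions of one group are not independent. With windows of 500 bp 11.6% of the regions higher in animal 2 and 4 of 91 higher in animal 1 lay on X (Fisher's exact p = 0.0818), the count of differing regions was 212, and without the filter on the number of libraries it was 214. The exact McNemar test called 0, with 677 at an unadjusted p under 0.05.

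**Figure D5:**
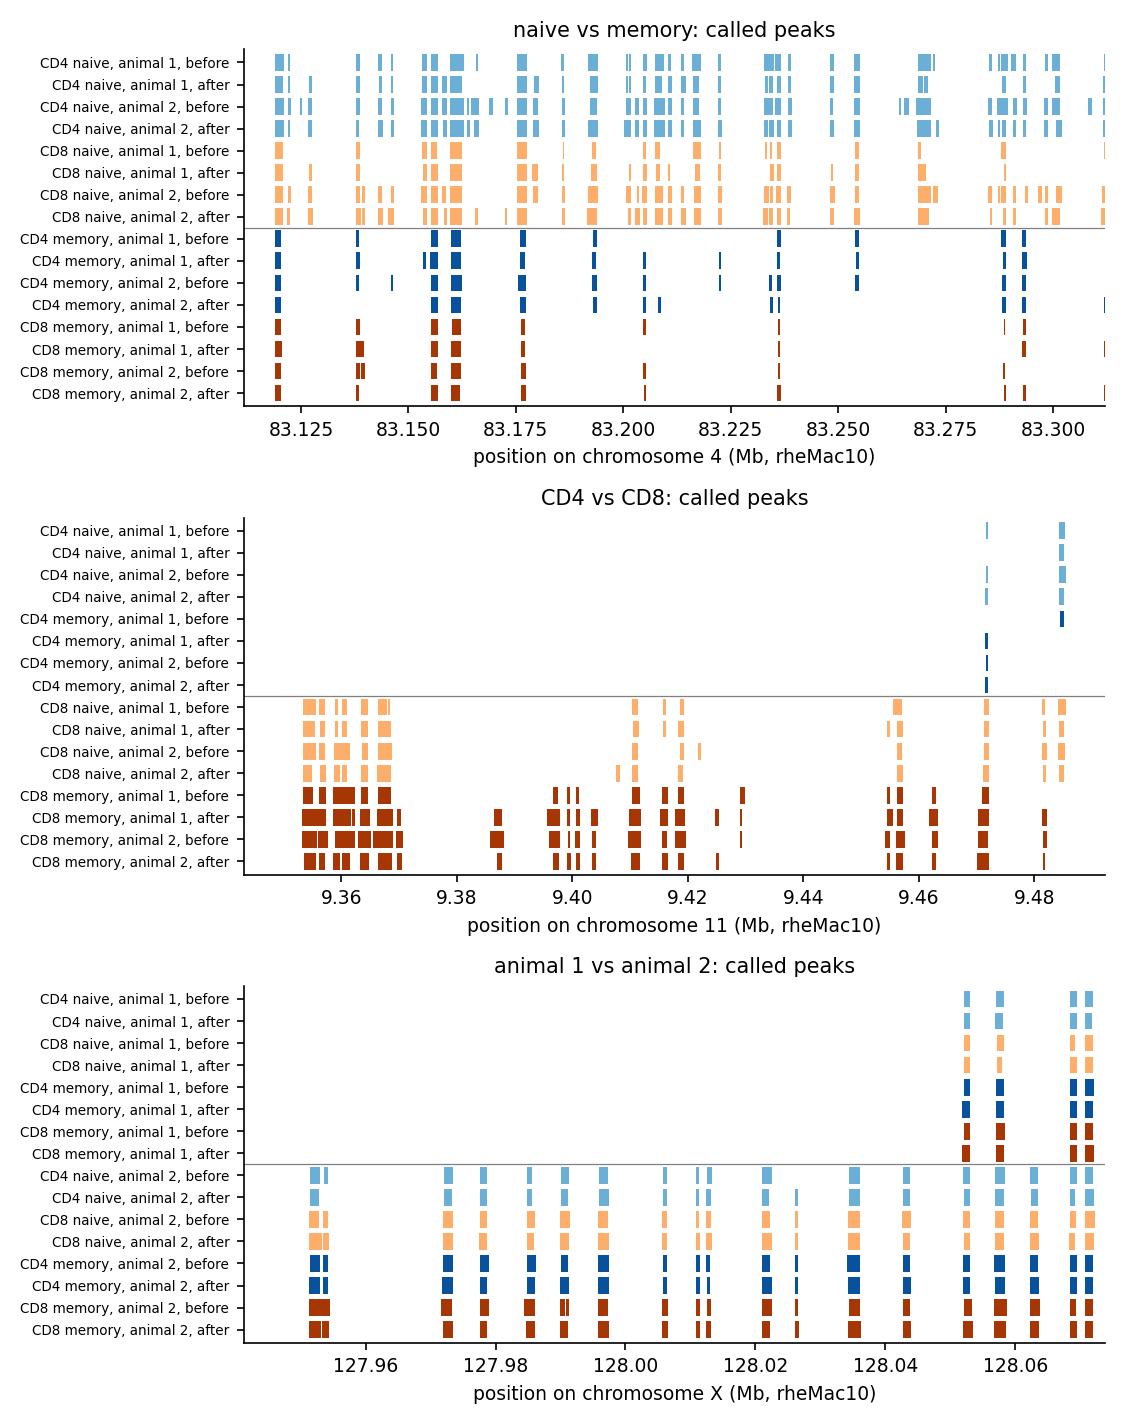
Called peaks (blocks) of the 16 libraries (rows) along 3 stretches of the genome (horizontal axes, Mb in rheMac10), coloured by population. The grey lines part naive from memory libraries on chromosome 4, CD4+ from CD8+ libraries on chromosome 11, and animal 1 from animal 2 on chromosome X. The stretches hold 16 naive, 8 CD8+ and 14 animal 2 regions that passed the test.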

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

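The recomputation at equal list length, the splits that part matched pairs and those that keep before and after libraries together were chosen after the result was seen. A difference between groups drew attention to the likeness of naive and memory peak sets, whose mean Jaccard index was lower in CD8+ than in CD4+ cells by a difference of -0.0861 (0.667 against 0.754, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.100). With lists of equal length the difference was -0.0857, and each of the 4 CD8+ values, 0.649 to 0.690, lay below each CD4+ value, 0.754 to 0.760. A second difference between groups was that of CD4+ with CD8+ peak sets, whose mean Jaccard index was lower in memory than in naive cells by -0.0473 (0.712 against 0.760, n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.100). With lists of equal length it was -0.0509. Both permutation tests ignored the matching by animal and time. No technical explanation beyond list length was tested for either difference. No library stood apart in 16 groups of 4 tested for peak number, bases covered, median width and share of peaks on X, where chance would mark about 1 in 20 groups.

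Other splits of the libraries bear on whether chance could give such counts. For naive against memory cells 1 of 100 splits of the 16 libraries, the real one, gave as many as 2930 regions, and the highest other split gave 0. The same held for CD4+ against CD8+ cells (783 regions, 1 of 100 splits, highest other 0) and for the 2 animals (383 regions, 1 of 100 splits, highest other 0). Within CD4+ cells 1 of 35 splits gave as many as the 2344 regions that separated the states, the highest other giving 686. Within CD8+ cells 1 of 35 gave as many as 4114, the highest other giving 499. For the lineages the numbers were 1499 regions in naive cells (1 of 35, highest other 801) and 3108 in memory cells (1 of 35, highest other 539). Regions set apart in a population, open or missing there alone, numbered 245 in naive CD4+, 200 in memory CD4+, 353 in naive CD8+ and 1405 in memory CD8+ cells. In each case 1 of 100 sets of 4 libraries, the real one, gave as many, with a highest other of 22. The libraries are matched by animal and time. Of 100 splits that part all matched pairs, the real one alone gave as many regions for state, lineage and animals, with a highest other of 0. Of 100 sets with 1 library of each animal and time, the real one alone gave as many regions set apart in each population, with a highest other of 4. Within a lineage or state only 8 splits part the 4 pairs, too few for a share under 0.05. Among them the highest other gave 19 regions against 2344, 40 against 4114, 28 against 1499 and 28 against 3108.

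All these splits exchange single libraries and so can take the before and after libraries of one population of one animal apart, although these were the most alike on average. With the 2 kept together, 35 splits of 8 such pairs into 4 and 4 remain, among them those by state, by lineage and by animal. The splits as large as the real one were 1, 2 and 3 of 35 for state, lineage and animals, but these were the 3 real splits themselves, so the rank of their counts fixes this number and it tells nothing of chance. Each comparison was therefore set against the splits that follow neither of the other 2. Of 33 such splits 1, the real one, gave as many as 2930 regions for the states, 783 for the lineages and 383 for the animals, with a highest other of 51 in each case. That share, 0.0303, was the smallest that 33 splits allow. The 33 were chosen after the result was seen, so this alone does not exclude chance. Only 8 splits also part the matched pairs, too few for a share under 0.05, and the highest other among them gave 0. Within a lineage or state 3 splits remain, again too few, with highest others of 686 against 2344, 499 against 4114, 801 against 1499 and 539 against 3108. For a population there are 28 sets of 2 such pairs. Sets as large as the real one numbered 3 for naive CD4+, 4 for memory CD4+, 2 for naive CD8+ and 1 for memory CD8+ cells. These were sets of the populations themselves, so the rank of their counts fixes this number. With the other 3 populations left aside 25 sets remain. The real set alone gave as many as 245 regions in naive CD4+, 200 in memory CD4+, 353 in naive CD8+ and 1405 in memory CD8+ cells. The highest other gave 154. That share, 0.04, was the smallest that 25 sets allow. The 25 were chosen after the result was seen, so this alone does not exclude chance. With 1 animal on each side, no split bears on other animals.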

How the results depend on the processing

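The animal comparison, its alternatives, the test with animals as strata and the 2 shortest lists left aside were added after the data were examined. No total count of regions, both directions together, changed by over 1.5 times with lists of equal length, a stricter threshold, coverage of 50% of a region or autosomes only in the comparisons of state, lineage, treatment and animals, or in the 4 comparisons within a lineage or state. Counts of 1 direction did at the stricter threshold: memory regions in CD4+ cells were 832 instead of 1353, CD8+ regions in naive cells 454 instead of 735, naive regions in CD8+ cells 1113 instead of 1713, and CD4+ regions in memory cells 993 instead of 1512. Fewer peaks entered there. The treatment comparison gave 0 regions in Fisher's exact test under each alternative run, with 39 to 229 at an unadjusted p under 0.05 across the definitions of peaks and regions. Without the filter on the number of libraries the counts were 1664 instead of 2930 for state, 379 instead of 783 for lineage and 214 instead of 383 for the animals, as more regions entered the adjustment. With the replicate block as the exact McNemar test they were 0, 0 and 0, with 2928, 1555 and 677 at an unadjusted p under 0.05, because its smallest p of 0.00781 would need 1707 regions at that value. With animals as strata the block gave 3191, 783 and, for treatment, 0. Each animal alone gave 0 regions for state and 0 for lineage, because 4 against 4 has a smallest p of 0.0286 and a call would need 2261 regions at that value in animal 1 and 2214 in animal 2. Windows of 500 bp gave 212 regions for the animals, and the cause was not tested. Regions changed the same way in both animals numbered 943, 904, 611 and 972 in naive CD4+, memory CD4+, naive CD8+ and memory CD8+ cells with coverage of 50%, and 1900, 1758, 1147 and 1700 with windows of 500 bp, where more regions were counted. Leaving out each library in turn gave 3070 to 3373 regions for state, 818 to 1878 for lineage, 0 for treatment and 403 to 456 for the animals. Within CD4+ and CD8+ cells it gave 2548 to 2710 and 4286 to 4995, and between lineages 1633 to 1779 in naive and 3359 to 3780 in memory cells. Counts of complete separation within a lineage or state can only stay or rise when a library is left out, so these ranges are no check of them. In the comparisons of state, lineage and animals the count rose with any 1 library left out, and the cause was not tested. The mean change in peaks was -109.9 with the stricter threshold and ran from -34.7 to 478.4 with each pair left out, and no value passed its test. The excess of similarity between times over that between animals was 0.0320 to 0.0339 under its 3 alternatives. For changes in both animals no library could be left out. The gene, gene list, motif and promoter alternatives were not run for want of an rheMac10 annotation. Depth was unknown, so its effect on list length could not be measured.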

Other observations

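Tests in this part were chosen after the data were examined, except the splits of the 16 libraries. Regions open in memory CD8+ cells alone lay close together, with 349 of 944 (37.0%) within 50 kb of another of the same kind. The share was 25.0% of 168 in memory CD4+, 21.2% of 212 in naive CD8+ and 9.09% in naive CD4+ cells, although larger sets lie closer by chance and this was not tested. The largest memory CD8+ groups held 8 regions on chromosome 16 from 9831642 to 9941170, 6 on chromosome 1 from 157090682 to 157258381 and 6 on chromosome 6 from 146311088 to 146355231. Memory CD4+ cells had 7 regions of their own on chromosome 2 from 14673713 to 14752328. On chromosome 7 naive CD8+ cells had 6 between 154624111 and 154709009, and memory CD4+ cells had 4 between 154886123 and 154929352. In the comparison of states the largest share of tested regions differed on chromosome 2, with 240 of 745 (32.2%), and the smallest on chromosome X, with 58 of 300 (19.3%).

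Weak differences between the times were counted against other splits of the pairs. At an unadjusted p under 0.05 there were 42 regions, and 72 of 100 splits of the 16 libraries gave as many, with a highest other of 2958, because those splits mix states and lineages. Among 100 splits that part all 8 before-after pairs, and so balance population and animal, the real split alone (1 of 100) reached 42, with a highest other of 39 and a median of 16. With lists of equal length 1 of 100 gave as many as 58 (highest other 56), with coverage of 50% 3 gave as many as 78 (highest other 96), and with windows of 500 bp 4 gave as many as 229 (highest other 326). With the stricter threshold 7 gave as many as 45 (highest other 57), a share over 0.05. The splits that part the pairs were chosen after the result was seen, so the shares under 0.05 alone do not exclude chance either. A small change over treatment may be present among weak peaks, but it depends on the threshold and cannot be parted from time.

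Memory regions defined in the other animal were open in naive libraries in 12.7% ± 2.57 of cases before and 10.3% ± 2.35 after (SD, n = 4 each), lower in 4 of 4 pairs (exact sign-flip p = 0.125, the smallest that 4 pairs allow), and lower in 3 of 4 with the stricter threshold. List length as the whole cause is argued against, since the change was -3.65 points at equal length, again lower in 4 of 4 pairs. A loss of weak peaks of any kind stays open, because naive regions in memory libraries changed by -0.509 points and were lower in 2 of 4 pairs. A smaller number of memory cells in the naive sort after treatment also stays open and was not tested.

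Animal 2 had more regions of the X chromosome. List length is argued against, since 16.1% of the regions higher in animal 2 lay on X at equal length, where 2.82% of the tested regions did (Fisher's exact test against animal 1, p = 2.21e-06). A variant of 1 locus is argued against as the whole cause, as the 31 regions lay in 12 loci over 50 kb apart, though 14 were in 1 of them. A different number of X chromosomes, as between a female and a male, stays a candidate explanation: the share of peaks on X was higher in animal 2 in 8 of 8 pairs, by 0.213 percentage points (2.75% against 2.54%, exact sign-flip p = 0.00781, adjusted p = 0.125). With 1 animal on each side it cannot be told apart from other differences between these individuals, and the labels used here give no sex.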
